A study of Mus musculus with 4 samples.

How the data were processed

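Drop-seq, a droplet method that barcodes the transcripts of single cells and counts molecules by unique molecular identifiers (UMIs), was run on vaginal epithelium of C57BL/6 mice. The design has 4 libraries: 2 from ovary-intact mice, named WT in the labels, and 2 from surgically ovariectomised mice, named OVX. Each library is described as a pool of 5 mice. The series text speaks of pooled samples run in duplicate, so it is unclear whether the duplicates of a group came from separate pools. P-values of the gene tests between groups then measure only the spread between these libraries, which may be technical. Tissue was digested with pronase and the epithelium was separated by hand under a microscope, per the labels' protocols.

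The deposited files hold raw UMI counts per gene and cell barcode, 1 matrix per library, with no normalization by the authors. The build mm10 and Seurat 2 are named in the submitters' processing notes. The aligner, the annotation and the rule by which barcodes were kept are not given in the sources used here. The matrices hold 3000 barcodes in WT library 1, 2000 in WT library 2, 3000 in OVX library 1 and 2000 in OVX library 2, with 25071 gene symbols over the 4 libraries and 15085 in all of them. The build and the annotation behind positions and shared sequence are those of GENCODE vM21, which may differ from the one used for counting; 94.1% of the symbols matched it. Genes with near-identical copies are uncertain, and for named genes the share of 50-base words in the last 500 bases of the transcript that also occur in other genes was computed.

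Cells with at least 200 detected genes and at most 20% mitochondrial UMIs were kept, which left 8446 cells. Scrublet called 26 of them (0.308%) as doublets in separate runs per library. A caller that marks so few cells has not worked, so doublets remain in the data; the 26 cells were removed, leaving 8420. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes and 30 principal components were used for a graph of 15 neighbours and Leiden clustering at resolution 0.8, without integration of the libraries (scanpy 1.11.5, leidenalg 0.10.2). Clusters were named from fixed markers when at least 3 were detected and higher in the cluster. The thresholds for a higher marker (log2 fold 0.25, detected in 5% of cells, at least 10 cells per library) were set after clusters had been seen, in trial runs with several clusterings. Under them 1 cluster of 1084 cells had 1 basal marker and stayed unnamed, although 82.4% of its cells held a UMI of Krt5 or Krt14. It was left out of the epithelial class, and counting it as basal-like was added as an alternative. Basal-like cells were clusters 0, 2 and 6. Differentiated cells were suprabasal-like clusters 5, 7 and 11 and luminal-like cluster 3. Proliferating clusters 4, 8, 9 and 10 counted as epithelial and entered neither class. In cluster 5 the leading 10 genes held 2 suprabasal and 2 cornified markers. The macrophage-like cluster was led by MHC class II genes, with 4 macrophage and 4 dendritic markers among its leading 10 genes.

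UMI counts were summed per library and class, since cells are not replicates. The sums were tested with edgeR 4.0.16 (TMM normalization, filterByExpr, quasi-likelihood F-test, OVX against WT, no covariates, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are UMIs per 1000000 UMIs of the class (CPM), as mean ± SD of 2 libraries. Fold changes are edgeR estimates. For a gene with 0 counts in every library of a group, a lower bound on the fold was computed against 3 counts over the group; with 1 to 3 counts in a group, the ratio of pooled counts is given with its 95% counting interval. The difference between basal-like and differentiated cells was tested as an interaction, with the library as a block. Its p-values leave out the spread between libraries that both classes share. Gene lists were tested in epithelial cells with camera (limma 3.58.1, preset correlation 0.01, two-sided), and again with an estimated correlation. Camera sets the members of a list against the other genes. With the preset correlation its degrees of freedom come from the number of genes, so small p-values do not reflect replication. With an estimated correlation they come from the libraries, which leave only 2. The 30 lists were: cell cycle S phase, cell cycle G2M phase, oestrogen response, basal keratinocyte, suprabasal keratinocyte, cornified envelope, simple epithelial and mucin, hormone receptors, Wnt pathway, Notch pathway, BMP and TGF-beta pathway, EGF family, antimicrobial and alarmin, chemokines and cytokines, interferon response, MHC class II, extracellular matrix, cholesterol synthesis, glycolysis, oxidative stress and glutathione, retinoid metabolism, immediate early and dissociation, mitochondrially encoded, and markers of fibroblasts, smooth muscle, endothelium, macrophages, neutrophils, T or NK cells and erythroid cells. The 23 lists with at least 3 tested members entered the test.

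Named genes followed a rule: per comparison the 12 largest rises and 12 largest falls among genes past the threshold with at least 50 CPM in the higher group and no overlap between the groups' libraries, leaving out mitochondrially encoded, ribosomal protein, haemoglobin, Gm-numbered and Rik genes; up to 6 members of each list past the threshold, or the 3 with the highest CPM where none passed; and Esr1, Pgr, Krt5 and Krt14 always. Some genes that the rule selects are not reported here, and counts over named genes leave them out. Lists, markers, this rule and the main tests were fixed before the data were examined.

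A cell counted as cycling with at least 3 UMIs of the S and G2M lists after thinning every epithelial cell to 400 UMIs, leaving out shallower cells. Shares were compared by an exact two-sided permutation of the libraries, which cannot give a p below 0.333 with 2 against 2. Intervals of shares are exact binomial, 95%, and cover counting error only.

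The scripts were tested on simulated counts with 200 changed genes drawn at the real means and library sizes. At a 2-fold change, 0% of changed genes were recovered for epithelial cells, 3% for basal-like cells, 0% for differentiated cells and 3% for whole libraries. At a 4-fold change, the shares were 28%, 38%, 18% and 43%. Between 1 and 3 unchanged genes were called in each run. In the runs for group comparisons all genes shared a common dispersion, 0.125 to 0.13, and libraries were drawn independently. Differences in dispersion between genes and the crossed deviations of the real libraries, described below, were not simulated. These recovered shares and false calls may therefore not hold for the real data. For the interaction, 22% were recovered at 2-fold and 89% at 4-fold, with a dispersion of 0.02 and an SD of 0.3 log2 units between libraries, shared by both classes of a library. Both were assumed rather than estimated, and the recovered shares depend on them. In the epithelial list simulation camera called 2 of 2 changed lists and 0 of 20 unchanged ones. Genes were drawn independently there, so it does not measure false calls for lists whose members vary together. The estimated correlation in the real data was 0.15 for the G2M list and 0.249 for the simple epithelial and mucin list. The gene tests therefore see large changes, and the smallest called fold in epithelial cells was 3.31.

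Alternatives covered size factors (RLE), DESeq2 1.42.0, the gene and cell filters, doublets, thinned sums, limma-trend on mean log values per cell, the clustering, the replicate number as a block and leaving out each library. Duplicate deposits were checked: the counts of the WT libraries differed by a chi-square of 42.5 per degree of freedom and those of the OVX libraries by 7.73, so all 4 were kept as separate libraries.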

Results

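Single-cell transcriptomes of the vaginal epithelium were compared between ovary-intact and ovariectomised mice, to describe how the epithelium differs once the ovaries, the main source of oestrogen and progesterone, are removed. The total was 5845107 UMIs in WT library 1, 1934634 in WT library 2, 991112 in OVX library 1 and 1684967 in OVX library 2. Cells kept numbered 2978, 1978, 1557 and 1907, with median UMIs per cell of 1597, 798, 431 and 738. The median mitochondrial share per cell was 4.00% and 3.85% in the WT libraries against 8.94% and 9.69% in the OVX libraries. The nuclear RNA Malat1 took 0.336% and 0.464% of UMIs in the WT libraries against 2.49% and 1.81% in the OVX libraries.

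In epithelial cells Krt14, Krt16 and Krt6b were lower after ovariectomy and Krt8 and Krt18 were higher. Krt14, a basal keratin (chromosome 11, 100203162 to 100207548), fell from 17200 ± 561 to 1970 ± 284 CPM (SD, n = 2 libraries per group), a log2 fold change of -3.23 ± 0.56 (SE; edgeR adjusted p = 0.0142). Krt16, a keratin of activated stratified epithelium, fell from 2300 ± 1730 to 4.48 ± 3.03 CPM (log2 fold change -8.85 ± 0.93, edgeR adjusted p = 0.00252), with 16.9% of its end sequence shared with other genes. Krt6b fell from 1340 ± 7.05 to 0.331 ± 0.468 CPM, a pooled ratio of 2600 with a counting interval of 466 to 103000. The metallothionein Mt4, the neuronal growth protein gene Gap43 and the desmosomal cadherin Dsg1a had 0 counts in both OVX libraries and were at least 224-fold, 190-fold and 49.4-fold lower. Krt8 (chromosome 15, 101996698 to 102004482) rose from 0.791 ± 0.387 to 132 ± 17.6 CPM and Krt18, its partner in simple epithelia, from 3.85 ± 0.573 to 420 ± 146 CPM, with edgeR adjusted p = 0.0018 for each.

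The flavin monooxygenase Fmo2 rose from 3.66 ± 1.41 to 1200 ± 319 CPM (log2 fold change 8.13 ± 0.63, edgeR adjusted p = 0.0018). The chemokine Cxcl17 had 0 counts in both WT libraries and was at least 311-fold higher in OVX. The alcohol dehydrogenase Adh1 rose from 0.517 ± 0.732 to 233 ± 132 CPM and the carboxylesterase Ces1d from 0.611 ± 0.111 to 143 ± 42.1 CPM. Camk2n1, the tight junction gene Cldn3, the interferon-induced Ifit1, the matrix gene Postn and Ltbp2 rose from at most 2 counts in the WT libraries, with pooled ratios of 400 (counting interval 70.1 to 15900), 340 (59.5 to 13600), 265 (46.0 to 10600), 245 (66.5 to 2050) and 297 (80.8 to 2470). The small nucleolar RNA Snord42a was also among the largest rises, at 0.525 ± 0.0106 against 71.2 ± 87.5 CPM, with 9.33 CPM in OVX library 1 and 133 in OVX library 2, and was not tested without OVX library 2. The remaining falls included Csta1 (pooled ratio 181, interval 61.8 to 878), Calm4 (166, 29.7 to 6570), Dsg1b (171, 30.6 to 6780), Sprr2f (88.2, 24.3 to 730) and Spink12 (70.9, 19.5 to 587). BC100530 fell from 2620 ± 1030 to 21.2 ± 16.8 CPM, and the decoy interleukin-1 receptor Il1r2 from 992 ± 6.64 to 11 ± 2.29 CPM. BC100530 shares 41.5% of its end sequence with other genes.

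Among hormone receptors, the progesterone receptor Pgr, a target of oestrogen signalling, fell from 123 ± 37.0 to 15.1 ± 4.86 CPM (log2 fold change -3.05 ± 0.51, edgeR adjusted p = 0.0123). Without OVX library 1 its adjusted p was 0.0923, and without OVX library 2 it was 0.162. The oestrogen receptor Esr1 stood at 96.1 ± 24.4 CPM in WT and 165 ± 41.9 in OVX (edgeR adjusted p = 0.462) and did not pass the threshold. Krt5, the partner of Krt14, stood at 13800 ± 11200 CPM in WT and 2560 ± 627 in OVX (edgeR adjusted p = 0.087) and did not pass; its WT libraries differed widely. Without WT library 2 it passed, with an adjusted p of 3.82e-06.

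**Figure D1:**
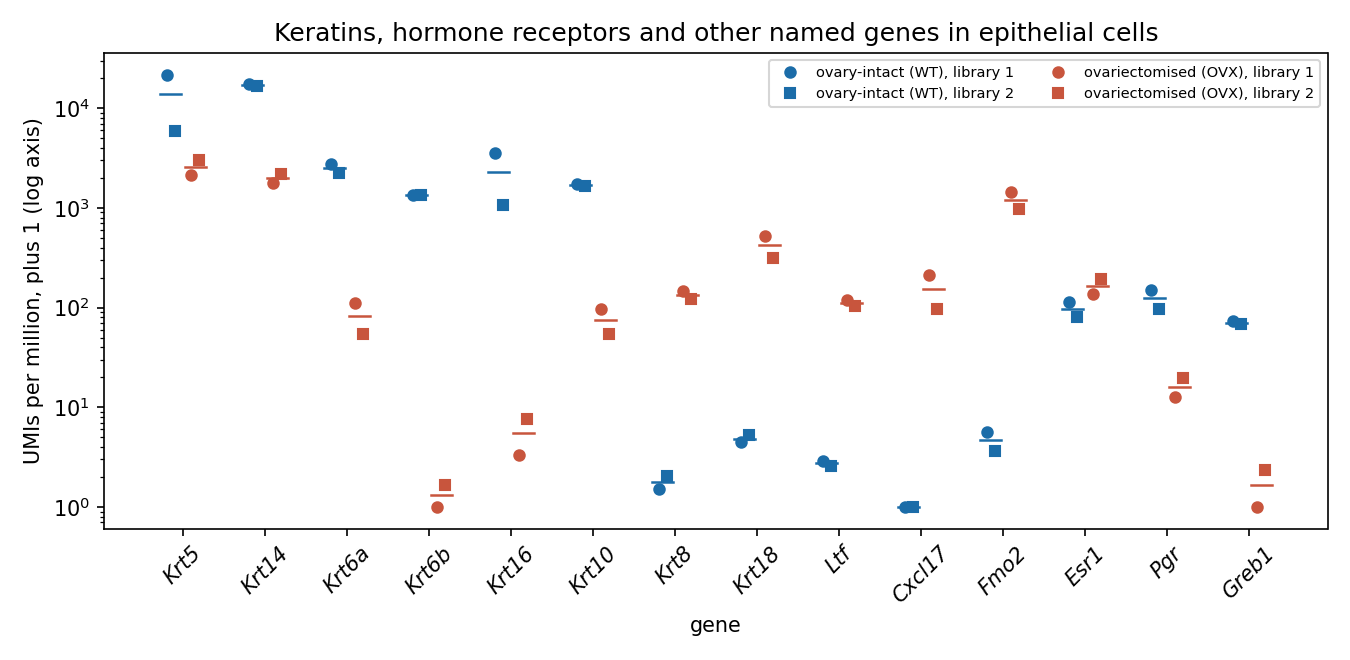
Levels of 14 named genes in epithelial cells, as CPM plus 1 on a log axis; each point is 1 library (n = 2 per group) and each short line is the group mean. Krt14 fell from a mean of 17200 to 1970, Krt18 rose from 3.85 to 420, and the WT libraries lie far apart for Krt5.

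Of 11297 genes tested in epithelial cells, 554 passed the threshold, 292 higher and 262 lower in OVX. The libraries of the groups did not overlap for 49.3% of tested genes, against 33.3% by chance if the 4 libraries were exchangeable. Depth differed between libraries and they deviated in crossed pairs, as described below, so that chance level is only nominal. All 554 called genes were without overlap, so leaving out 1 library could hardly reverse their direction. Limits: the count was 1597 without WT library 1, 1543 without WT library 2 and 112 (90 higher, 22 lower) without OVX library 2, and limma-trend on mean log values called 0 genes (1965 at an unadjusted p under 0.05) where DESeq2 called 695. Of 90 named genes past the threshold, 36 also passed without each library in turn, 25 were lost without OVX library 1 and 53 without OVX library 2, with adjusted p up to 0.798 and no change of direction.

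The suprabasal list, genes of the layers above the basal cells, had 16 of 35 tested members lower in OVX and 0 higher, with 26 lower when adjusted over the list alone (camera adjusted p = 3.81e-19; adjusted p = 0.199 with an estimated correlation). Krt6a fell from 2520 ± 365 to 81.6 ± 39.6 CPM, Krt10 from 1690 ± 66.0 to 74.6 ± 29.7 CPM and Krtdap from 2340 ± 1040 to 63.8 ± 4.38 CPM. The cornified envelope list, genes of the outermost dead layer, had 10 of 17 lower and 0 higher, with 12 lower adjusted over the list alone (camera adjusted p = 1.86e-11; adjusted p = 0.2 with an estimated correlation). Its median log2 fold change was -4.18, or -2.62 with members at 0 counts set to their bound. Stfa3 fell from 198 ± 40.9 to 5.64 ± 1.38 CPM; Sprr2d, with 0 OVX counts, was at least 18.3-fold lower; Sprr2a3, which shares 77.8% of its end sequence with other genes, fell from 64.7 ± 35.7 to 3.99 ± 0.959 CPM. The basal keratinocyte list had 5 of 21 lower and 1 higher, and 9 and 1 adjusted over the list alone (camera adjusted p = 5.21e-05; adjusted p = 0.275 with an estimated correlation). Igfbp2 fell from 966 ± 45.1 to 17.9 ± 5.55 CPM, and Mt2 and Igfbp3 fell too. The simple epithelial and mucin list had 11 of 22 higher and 0 lower, with 12 higher adjusted over the list alone (camera adjusted p = 1.84e-11; adjusted p = 0.233 with an estimated correlation). Lactoferrin, Ltf, rose from 1.75 ± 0.212 to 110 ± 12.1 CPM, the immunoglobulin receptor Pigr from 0.525 ± 0.0106 to 43.2 ± 4.91 CPM and Wfdc2 from 59.7 ± 0.891 to 634 ± 53.5 CPM. The higher mitochondrial and Malat1 shares of the OVX libraries stand beside each of these groups. Cell composition differed as well. Suprabasal-like clusters 7 and 11 held 663 and 195 cells, 0 of them from OVX. Cluster 5 held 464 and 218 cells of the WT libraries and 2 and 2 of the OVX libraries. Luminal-like cluster 3 held 0 and 1 against 348 and 469. Sums over all epithelial cells cannot separate a change in cell kinds from a change in levels per cell.

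In the G2M list of cell cycle genes, 29 of 52 members fell after ovariectomy and 0 rose, with 38 lower adjusted over the list alone (camera adjusted p = 3.82e-27; adjusted p = 0.232 with an estimated correlation). Ube2c, which marks proteins for destruction in mitosis, fell from 228 ± 56.2 to 6.46 ± 5.84 CPM, Birc5 from 215 ± 38.3 to 15.4 ± 1.25 CPM and the mitotic kinase gene Cdk1 from 118 ± 14.2 to 10.4 ± 4.88 CPM. Cdca3, Ccnb2 and Cdca8 fell as well. In the S phase list 9 of 42 fell and 0 rose, with 19 lower adjusted over the list alone (camera adjusted p = 1.28e-12; adjusted p = 0.233 with an estimated correlation). Rrm1 and Rrm2, subunits of the enzyme that makes deoxynucleotides, fell from 257 ± 32.0 to 36.9 ± 0.655 CPM and from 104 ± 33.3 to 10.5 ± 1.70 CPM. After thinning to 400 UMIs, 47.7 ± 5.54% of epithelial cells (SD, n = 2) in WT and 20.1 ± 2.85% in OVX held at least 3 UMIs of both lists together (exact permutation p = 0.333, the smallest this design allows). With at least 2 UMIs the shares were 62.3 ± 6.61% and 38.5 ± 6.16%, and with at least 5 UMIs 32.5 ± 5.41% and 5.76 ± 1.63%. Thinning left out 36 WT and 168 OVX cells, and the unthinned shares were 77.4 ± 19.0% and 41.1 ± 18.6%. In a clustering made without the genes called changed in whole libraries, proliferating clusters held 30.8 ± 4.01% of epithelial cells in WT and 1.57 ± 0.284% in OVX (exact permutation p = 0.333). Higher mitochondrial and Malat1 shares in OVX stand beside these falls. Free RNA from broken cells can add cycle UMIs to any cell. Macrophage-like cells held Mki67 at 1160 CPM in WT library 1 (14 cells), 213 in OVX library 1 (17 cells) and 407 in OVX library 2 (26 cells). Their cluster also had 9 proliferating markers, so these values cannot separate free RNA from division of those cells. The share of free RNA among cycle UMIs in each group therefore stays unknown.

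**Figure D2:**
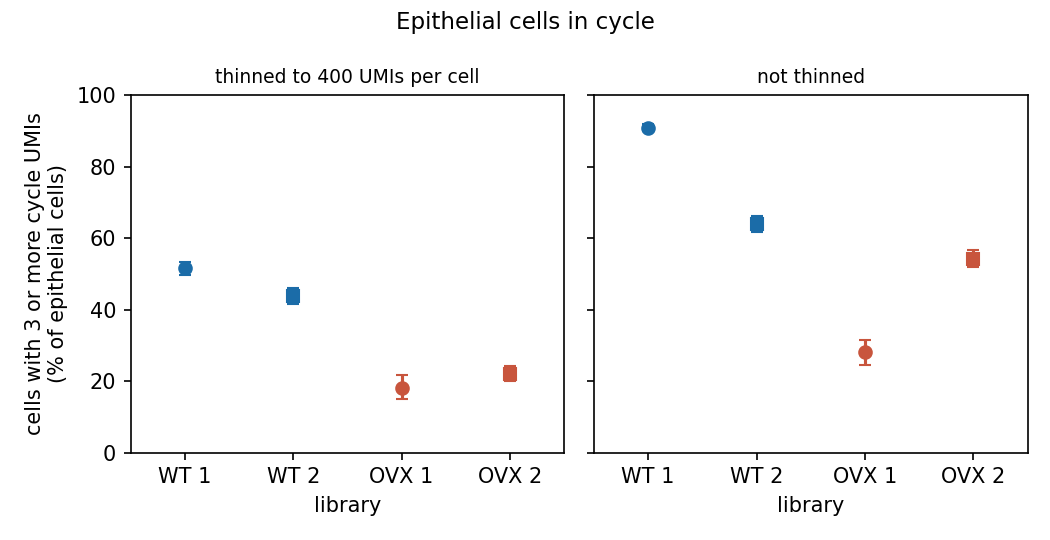
Share of epithelial cells with at least 3 UMIs of the cell cycle lists in each library, thinned to 400 UMIs per cell (left) and not thinned (right); bars are exact 95% binomial intervals, which cover counting error only. Thinned shares were 51.6% and 43.7% in the WT libraries and 18.1% and 22.1% in the OVX libraries.

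The cholesterol synthesis list had 3 of 22 lower, among them Sqle and Mvk, and 12 adjusted over the list alone (camera adjusted p = 6e-07; adjusted p = 0.232 with an estimated correlation). The glycolysis list had 3 of 17 lower, and 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 7.46e-07; adjusted p = 0.232 with an estimated correlation). The glucose transporter Slc2a1 fell from 298 ± 1.38 to 17.3 ± 1.97 CPM and Pkm from 521 ± 91.2 to 112 ± 7.14 CPM, while Slc16a3, a lactate exporter, had a pooled ratio of 57.4 (10.2 to 2280). The retinoid list had 3 of 6 lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 0.0231; adjusted p = 0.303 with an estimated correlation). Crabp2, which binds retinoic acid, fell from 338 ± 75.9 to 81.9 ± 6.87 CPM, Lrat fell, and Rdh10 rose from 9.45 ± 8.10 to 76.4 ± 10.7 CPM. The retinoid call was lost without WT library 1, without WT library 2 and without OVX library 2, at camera adjusted p = 0.136, 0.052 and 0.144, and with no gene filter, at 0.591. The mitochondrial and Malat1 shares were higher in OVX here too.

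The BMP and TGF-beta list had 4 of 21 higher and 1 lower, and 8 and 3 adjusted over the list alone (camera adjusted p = 0.0174; adjusted p = 0.234 with an estimated correlation). Id4, an inhibitor of differentiation factors, rose from 5.85 ± 0.747 to 105 ± 32.7 CPM, Id2 and Id3 also rose, Inhba rose with a pooled ratio of 39.6 (9.61 to 349), and Tgfb2 fell from 172 ± 6.84 to 47.0 ± 9.40 CPM. That list did not pass without WT library 2 (camera adjusted p = 0.052), without OVX library 1 (0.164) or without OVX library 2 (0.193). The chemokine list had 3 of 6 higher (Cxcl17, Csf1 and Cx3cl1) and 1 lower (Cxcl14), and 4 and 1 adjusted over the list alone (camera adjusted p = 0.00394; adjusted p = 0.233 with an estimated correlation). The interferon list had 2 of 12 higher, Ifit1 and Psmb8, and 6 adjusted over the list alone (camera adjusted p = 0.000208; adjusted p = 0.232 with an estimated correlation). The extracellular matrix list had 3 of 9 higher, Postn, Timp2 and Timp3, and 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.037; adjusted p = 0.423 with an estimated correlation). It did not pass without WT library 2 (0.052) or OVX library 2 (0.201). The EGF list had 1 of 10 higher, Dusp6, and 3 adjusted over the list alone (camera adjusted p = 0.0285; adjusted p = 0.303 with an estimated correlation), and did not pass without WT library 2 (0.0561), with no gene filter (0.0887) or with other blocks in the design (0.0571 and 0.0555). Beside these rises, too, mitochondrial and Malat1 shares were higher in OVX.

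A further 9 lists did not pass. The oestrogen response list was split: Ltf and the water channel Aqp5 rose, while Greb1, Cdkn1a and Pgr fell, 2 up and 3 down of 19, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.219). Greb1 fell from 69.8 ± 3.78 to 0.662 ± 0.936 CPM, a pooled ratio of 69.0 (19.0 to 571). The hormone receptor list had 1 of 10 lower, Pgr, also adjusted over the list alone (camera adjusted p = 0.665). The Wnt list had 4 of 25 higher (Wnt11, Fzd3, Sfrp1 and Tnfrsf19) and 1 lower (Fzd6), and 4 and 3 adjusted over the list alone (camera adjusted p = 0.0606, and 0.00776 without WT library 1), and the Notch list had Hey1 higher and Cdkn1a lower of 16, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.138). The antimicrobial list had 4 of 9 higher (Ltf, Pglyrp1, Defb1 and Il33) and 2 lower (Il1f9 and Wfdc18), or 4 and 3 adjusted over the list alone (camera adjusted p = 0.229). The oxidative stress list had 2 of 25 higher (Mgst1 and Aldh3a1) and 1 lower (Txn1), or 2 and 3 adjusted over the list alone (camera adjusted p = 0.578), and the dissociation list had 1 of 21 higher, Fosb, or 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.305). Fosb lost its call without WT library 1 (adjusted p = 0.0761) and WT library 2 (0.0602). It was not tested without OVX library 1 or 2. The mitochondrially encoded list had 0 of 10 past the threshold by either adjustment (camera adjusted p = 0.0511, and 0.00992 without WT library 2); mt-Rnr2 stood at 29800 ± 5580 CPM in WT and 78900 ± 5110 in OVX (edgeR adjusted p = 0.296). Of markers of other cell types, the fibroblast list had 1 of 5 higher, Postn, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.469). Too few members were tested for a list test of smooth muscle (2, with 0 past the threshold), endothelium (1, Ramp2, higher), neutrophil (1, Il1r2, lower) and T or NK markers (1, Trbc2, lower), and 0 MHC class II, macrophage and erythroid genes were tested.

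**Figure D3:**
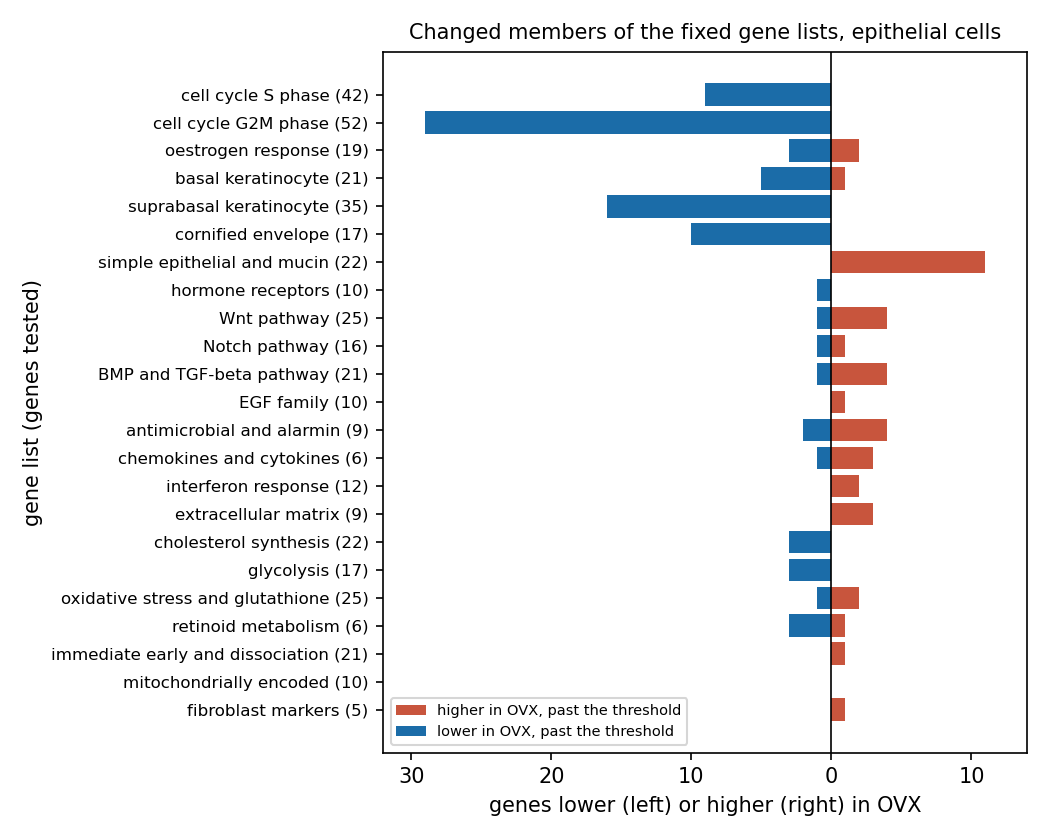
Number of members of each of the 23 tested gene lists that passed the edgeR threshold in epithelial cells, lower in OVX to the left and higher to the right; the number of genes tested is in parentheses. The G2M list has 29 members to the left and the simple epithelial and mucin list 11 to the right.

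Basal-like clusters 2 and 6 were led by Gap43 and Il1r2 and named on markers that included Krt5 and Krt14. Cluster 0 was named on 7 markers without Krt5 or Krt14, and 0 basal markers were among its leading 10 genes. Tests of these genes in basal-like cells therefore partly reuse genes that formed or named the clusters. Basal-like cells came from cluster 0 in OVX, and in WT from clusters 2 and 6 apart from 20 and 3 cells of cluster 0. In them Krt14 fell from 20600 ± 1060 to 2760 ± 71.8 CPM (SD, n = 2; log2 fold change -2.96 ± 0.56 SE, edgeR adjusted p = 0.00864) and Krt5 from 17300 ± 13800 to 2370 ± 618 CPM (adjusted p = 0.0278). Without OVX library 1 neither passed, at adjusted p = 0.0542 and 0.0994. Krt6a fell from 1990 ± 118 to 13.0 ± 5.40 CPM and Il1r2 from 1900 ± 63.9 to 14.8 ± 5.08 CPM. Gap43, Krt6b and the retinol-binding Rbp2 had 0 OVX counts and were at least 236-fold, 51.6-fold and 15.5-fold lower. In WT library 1, 14 macrophage-like cells held Krt6a at 2320 and Krt6b at 1900 CPM, and basal-like cells held 2080 and 110 CPM. Free RNA or doublets were therefore not told apart from expression of Krt6a and Krt6b in WT basal-like cells. Greb1, Lrat and the gap junction gene Gjb2 fell with pooled ratios of 145 (25.8 to 5740), 115 (20.4 to 4570) and 115 (20.4 to 4570). Fmo2 rose from 2.42 ± 0.938 to 661 ± 65.6 CPM, and Krt18 had a pooled ratio of 212 (58.0 to 1760). In OVX libraries 1 and 2 Krt18 stood at 197 and 193 CPM in basal-like and 798 and 586 in luminal-like cells. The few fibroblast-like cells held 240 and 210 CPM and the macrophage-like cells 107 and 0. Free RNA was therefore not told apart from expression of Krt18 in OVX basal-like cells. Ces1d, the matrix proteoglycan Fmod, Cnksr2 and Ltbp2 had 0 WT counts and were at least 56.2-fold, 51.8-fold, 46.7-fold and 46.1-fold higher. Pgr fell from 208 ± 77.2 to 15.3 ± 5.80 CPM (edgeR adjusted p = 0.00324, and 0.0847 without OVX library 2), while Esr1 (85.2 ± 40.9 and 188 ± 51.2 CPM) did not pass.

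Of 8604 genes tested in basal-like cells, 387 passed, 181 higher and 206 lower in OVX, and 49.9% of tested genes did not overlap. The count was 1147 without WT library 1, 1209 without WT library 2, 232 without OVX library 1 and 69 (45 higher, 24 lower) without OVX library 2. Limma-trend called 3. Of 27 named genes past the threshold, 15 passed without each library in turn and the others had adjusted p up to 0.0994 or were not tested.

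Differentiated cells came from other clusters in each group: suprabasal-like clusters 5, 7 and 11 held most of them in WT, and cluster 3 in OVX. Krt6b, Mt4 and Dsg1a were among the leading 10 genes of cluster 7. Cxcl17 was among those of cluster 3, and Krt8 helped to name that cluster. Tests of these genes in differentiated cells therefore partly reuse genes that formed or named the clusters. Cluster 3 was named luminal-like on 10 luminal against 8 suprabasal markers. At resolution 0.4 its counterpart held 9 of each, and with no mitochondrial limit 605 OVX cells formed a suprabasal-like cluster (8 against 7) and 179 a luminal-like one. Krt6b fell from 3810 ± 148 to 1.06 ± 1.5 CPM, a pooled ratio of 2610 (468 to 103000), and Krt14 from 20700 ± 543 to 822 ± 48.5 CPM (log2 fold change -4.78 ± 0.56, edgeR adjusted p = 0.000644). Mt4, Dsg1a, Dsg1b, Gap43, the envelope gene Sprr2f and the protease inhibitor Cst6 had 0 OVX counts and were at least 222-fold, 43.7-fold, 39.5-fold, 33.8-fold, 24.2-fold and 17.7-fold lower. Fmo2 rose from 1.27 ± 1.80 to 1990 ± 231 CPM; Cxcl17 and Postn had 0 WT counts and were at least 284-fold and 148-fold higher. Krt8 rose with a pooled ratio of 595 (105 to 23600), and Stxbp6, Dnah5 and Iqgap2 were at least 82.0-fold, 77.1-fold and 62.4-fold higher. Pgr fell from 101 ± 25 to 16.3 ± 3.97 CPM (edgeR adjusted p = 0.0138, and 0.156 and 0.157 without OVX library 1 and 2), and Krt5 did not pass (14200 ± 11600 and 2830 ± 853 CPM, adjusted p = 0.0544).

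Of 7136 genes tested in differentiated cells, 456 passed, 269 higher and 187 lower in OVX, and 48.6% did not overlap. Since the class came from different clusters in each group, these calls cannot separate a change in levels from a difference in cell kinds. The count was 870 without WT library 2, 282 without OVX library 1 and 179 without OVX library 2, and limma-trend called 3.

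Sums over all kept cells, which need no cell type names, gave 613 changed genes of 11478, 319 higher and 294 lower in OVX by edgeR, with 50.2% of tested genes not overlapping. The count was 1576 without WT library 1, 1873 without WT library 2, 389 without OVX library 1 and 316 without OVX library 2, and limma-trend called 0 (2127 at an unadjusted p under 0.05) where DESeq2 called 785.

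The change differed between basal-like and differentiated cells for 607 of 8793 genes, 267 more positive and 340 more negative in differentiated cells. Krt10 fell from 4670 ± 22.7 to 97.9 ± 45.5 CPM in differentiated cells and stood at 161 ± 78.0 and 49.8 ± 1.02 CPM in basal-like cells (interaction log2 fold change -4.47 ± 0.37, edgeR adjusted p = 5.13e-30). The serine protease inhibitor Serpinb11 rose from 124 ± 9.20 to 1060 ± 29.9 CPM in differentiated cells and fell from 155 ± 13.3 to 23.5 ± 1.47 CPM in basal-like cells. The defensin Defb1 rose in basal-like cells from 3.30 ± 0.306 to 110 ± 12.4 CPM and stood at 18.8 ± 5.10 and 23.8 ± 8.29 CPM in differentiated cells. These 3 genes were chosen after their values were seen. Krt10 was a naming marker of suprabasal-like clusters 5, 7 and 11, which held most differentiated cells in WT. Serpinb11 led the genes of cluster 3, which held most of them in OVX. The interaction of Krt10 and Serpinb11 was therefore partly set by how the classes were formed. Without the library as a block 2 genes passed, and the count was 158 without WT library 1, 245 without WT library 2 and 233 without OVX library 2.

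Other cell types were rare. Macrophage-like cells made up 0.463 ± 0.0107% of cells in WT and 1.23 ± 0.192% in OVX, and fibroblast-like cells 0.0253 ± 0.0357% and 0.767 ± 0.176% (SD, n = 2; exact permutation p = 0.333 for each, the smallest possible). With at least 500 genes per cell, 0 fibroblast-like cells remained in every library. In WT library 1, 0 of 2978 cells were fibroblast-like, with an upper 95% limit of 0.124%. The epithelial class held 98.0 ± 1.66% of WT and 66.3 ± 31.7% of OVX cells. The unnamed cluster held 0.369% and 2.68% of the WT libraries and 54.4% and 9.07% of the OVX libraries, with a median of 410 UMIs per cell. A UMI of Krt5 or Krt14 was seen in 70.8% of 24 macrophage-like and fibroblast-like cells in WT (median 906.5 UMIs) and 20% of 70 in OVX (474.5 UMIs), against 99.8% and 88.0% of epithelial cells (1231 and 710 UMIs).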

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

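The test of mitochondrial share in cells of 500 to 1000 UMIs and the second form of the low-mitochondrial test were chosen after the results they examine had been seen, and length and shared copies were chosen as explanations after a look at the most extreme genes of the library pattern.

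The change after ovariectomy differed between basal-like and differentiated cells for 607 genes by the interaction test. The genes given here are the 6 largest in each direction with at least 50 CPM, a choice made after the values were seen. The change was more positive in differentiated cells for Postn (interaction log2 fold change 9.13), Nupr1 (8.23), Serpinb11 (5.76), Thsd4 (5.68), Plcb4 (5.06) and Serpinb2 (4.80). It was more negative for Them5 (-8.26), Ifi202b (-7.00), Fam81a (-6.35), Adam28 (-5.09), Defb1 (-4.83) and Krt10 (-4.47). Postn, Nupr1, Fam81a and Adam28 had a class and group with 0 counts, so their fitted values depend on the prior count and are not bounds. The class called differentiated came from suprabasal-like clusters in WT and from a cluster named luminal-like on 10 against 8 suprabasal markers in OVX, so the interaction also compares those clusters. No explanation was tested for it.

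WT library 1 deviated from its group together with OVX library 2, and WT library 2 with OVX library 1: over 3617 genes, the WT difference (library 1 minus 2) and the OVX difference correlated at -0.745, across genes, which are not independent replicates. Reads shared between copies were argued against as the whole cause by -0.725 among 2921 genes with no shared 50-base word. Transcript length and GC content were argued against by -0.664 in the residuals after both, although length correlated with the WT difference at 0.565 and with the OVX difference at -0.456. In cells of 400 to 800 UMIs the correlation was -0.617. WT library 1 and OVX library 2 were the deeper library of each group. The window did not equalise depth, with 134954 UMIs in 185 cells of WT library 1 and 569426 in 951 of WT library 2. OVX library 1 had 410729 UMIs in 747 cells and OVX library 2 had 627975 in 1044. A difference in UMIs per cell therefore stays open. A shared day or processing batch of each crossed pair could give such a pattern and stays open, since the labels name none; no biological explanation was tested.

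OVX cells held a larger mitochondrial share, and among cells of 500 to 1000 UMIs the lowest OVX median still exceeded the highest WT median by 4.31 percentage points, which argues against depth as the cause; median depths in that window were 855, 697, 640 and 684.5 UMIs, and WT library 2 and OVX library 2, the closest in depth, had median shares of 4.12% and 9.92%. Damaged cells might also account for the genes called changed. In epithelial cells of up to 5% mitochondrial UMIs, the median ratio of the log2 fold change to that in all cells was 0.953 (quartiles 0.553 and 1.24), but only 352 of 554 called genes (63.5%) were tested there, so this value excludes nothing; that reading follows a rule on missing genes applied after the value was seen. A second form over all 554 genes, added after that value was seen, gave 0.924 (bootstrap interval 0.856 to 0.975), with 54 genes in the other direction, and argues against damage seen by mitochondrial share as the whole cause; it rests on 46 and 53 OVX cells. Removal of the ovaries stays open as the biological explanation.

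Krt8, Krt18 and Krt19 were high in OVX. Copies of these genes are argued against, since at most 1.11% of their end sequence is shared. Free RNA spread over all cells could not be told apart: at 300 UMIs, 3.03% (exact 95% interval 0.369 to 10.5) of 66 OVX macrophage-like and fibroblast-like cells held a UMI of the 3 genes, against 7.19% of basal-like and 29.3% of luminal-like cells. The bound set in advance, an upper limit below 0.333 of the luminal-like share, was missed.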

How the results depend on the processing

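The crossed pairing, removal of the top 5% of doublet scores, cells of 400 to 800 UMIs, cells of up to 5% mitochondrial UMIs and the unnamed cluster counted as basal-like were chosen after seeing the data; the other alternatives were fixed before. Of 2905 alternative values of 152 results of named genes, 2534 kept direction and side of the threshold, 341 fell short of it (140 of them with limma-trend), 22 newly passed and 8 reversed, 0 of these in a gene past the threshold in the main analysis. The cause was not tested except where fewer cells or UMIs are part of the setting. Called genes had no overlap between the groups' libraries, so leaving out 1 library could hardly reverse them. Counts below are in the order epithelial, basal-like, differentiated, whole libraries (554, 387, 456, 613). No gene filter gave 1154, 648, 759 and 1346. Thinned sums gave 283, 124, 271 and 339, with fewer UMIs. Limma-trend gave 0, 3, 3 and 0. Leaving out 1 library gave 112 to 1597, 69 to 1209, 179 to 870 and 316 to 1873; a lone library is then assumed to vary like the other group. At least 500 genes per cell gave 194 in basal-like cells, and resolution 0.4 gave 249. Cells of 400 to 800 UMIs gave 212 in epithelial cells and 236 in whole libraries, and cells of up to 5% mitochondrial UMIs gave 106 in epithelial cells. With the unnamed cluster as basal-like, 590 epithelial genes passed, 503 of them shared with the 554.

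Replicate numbers were shared between groups but nothing says that they pair libraries. With the replicate block the counts were 496, 269, 295 and 521, and 13 lists in place of 14. The same-numbered libraries' deviations correlated at -0.745, and the crossed pairing as block, chosen after seeing the data, called 3060, 1764, 1846 and 3498 genes. Leaving out 1 library gave totals of 11 to 14 changed lists in place of 14, newly passing lists included, and with an estimated correlation 0 lists passed by camera (3 at an unadjusted p under 0.05; 14 with the preset correlation). The estimated correlations of the suprabasal and cornified envelope lists were -0.0135 and -0.0578, below the preset 0.01. A larger correlation is therefore not what removed those calls. The estimated form also tests on far fewer degrees of freedom, set by the number of libraries and not of genes. Few lists can pass under it. For the other lists the effects of the correlation and of the fewer degrees of freedom were not told apart. The EGF list fell short with the replicate block (camera adjusted p = 0.0571), no gene filter (0.0887) and the crossed pairing (0.0555), and the Notch list passed with no gene filter (0.0466). The interaction count of 607 was 2 with no library block, 370 with no gene filter and 158 to 543 without 1 library.

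The OVX minus WT difference in the epithelial share, -31.7 percentage points, was -0.544 with at least 500 genes per cell, -1.52 with doublets kept, -1.51 at resolution 0.4 and -1.38 in the clustering without changed genes. In the same settings the unnamed share, 30.2, was 0, 0, 0 and 0.0262, so the large difference rests on that cluster. The macrophage-like difference of 0.765 was 0.544 with at least 500 genes, where the cluster had 3 macrophage and 4 dendritic markers among its leading 10 genes, and 0.610 without changed genes, and the fibroblast-like difference of 0.742 was 0 with at least 500 genes. The cycling difference of -27.6 was -36.3 not thinned and -22.0 with at least 500 genes, where cells were thinned to 700 UMIs. Reversed log2 fold changes: in epithelial cells mt-Cytb (main -0.08) was 0.026 with the replicate block, 0.027 with the crossed pairing and between -0.58 and 0.63 without 1 library; mt-Rnr1 was -0.24 in cells of up to 5% mitochondrial UMIs; Notch3 was -0.24 in cells of 400 to 800 UMIs, -0.106 in cells of up to 5% mitochondrial UMIs and between -0.095 and 0.901 without 1 library. OVX library 1 held 428601 epithelial UMIs against 5798295 in WT library 1.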

Other observations

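Within the OVX libraries, epithelial cells fell into kinds that differed in keratins. Luminal-like cells of OVX library 1 and OVX library 2 held Krt18 at 798 and 586 CPM, Krt19 at 428 and 232 CPM, Gabrp at 600 and 386 CPM and Pigr at 90.2 and 119 CPM. Basal-like cells of the same libraries held Krt18 at 197 and 193 CPM and Trp63, a transcription factor of basal cells, at 438 and 252 CPM. The proliferating cells of OVX, 36 and 55 cells, held Mki67 at 1020 and 1950 CPM, and those of WT, 1056 and 723 cells, at 1850 and 660 CPM. These genes help define the clusters, so the values describe them and are not comparisons.

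The unnamed cluster held 1084 cells, of which 847 came from OVX library 1. Its cells in OVX library 1 held Krt5 at 2120, Krt14 at 2930 and Krt15 at 2290 CPM, with a median of 368 UMIs per cell, beside 1940, 2710 and 2630 CPM and a median of 554 UMIs in basal-like cells of that library. Its leading genes included the pseudogenes Rps19-ps9 and Rps6-ps3. In a clustering without the genes changed in whole libraries, basal-like clusters held 36.6 ± 3.46% of epithelial cells in WT and 74.2 ± 2.42% in OVX (SD, n = 2; exact permutation p = 0.333, the smallest possible), and differentiated clusters 32.5 ± 0.548% and 24.2 ± 2.70%.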
